A study of Urosaurus graciosus
Urosaurus ornatus and Urosaurus graciosus and Urosaurus ornatus with 18 samples.

How the data were processed

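Liver RNA was sequenced from 18 male lizards of the genus Urosaurus. Per the labels, 6 animals were U. graciosus, 6 were U. ornatus and 6 were hybrids, and 3 animals of each lineage were held at 36 °C and 3 at 40 °C for 48 h. RNA was extracted with TRIzol and RNeasy columns and made into directional Illumina libraries, per the labels. Per the submitters' processing notes, the authors trimmed reads with Trim Galore 0.6.4, aligned them with STAR to the genome of Sceloporus undulatus, a lizard of another genus, counted them with Subread and tested them with DESeq2. The genome build, annotation release, strand setting and treatment of reads with several matches are not given in the sources used here.

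The deposited table holds raw counts per gene from the authors, 22773 genes by 18 libraries, of which 9041 genes carry placeholder names instead of symbols. Totals ran from 15780346 to 35002548 counts per library. No genome or annotation file was used here, so no positions are given. Most low values were even numbers (71.8% to 76.4% of the counts from 1 to 20 in a library), so a count may not equal 1 fragment. Because the unit behind a count is unsure, the counts were also halved and rounded up as an alternative chosen after seeing the data. Intervals and floors cover counting error only.

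Genes were kept by edgeR's filterByExpr on the 6 groups, which left 15856. Libraries were scaled by TMM and fitted with edgeR 4.0.16 in R 4.3.3 by quasi-likelihood (robust, 1 mean per group, all 18 libraries). Contrasts were the mean heat effect (40 °C minus 36 °C) over 3 lineages, the heat effect in each lineage, the differences of these heat effects, and the lineage differences averaged over both temperatures. Benjamini-Hochberg adjustment ran over all genes tested in a contrast, with calls at an adjusted p under 0.05. A gene counted as outside both parents when the hybrids differed from each parent in the same direction, both past that threshold. For the 3045 genes that differed between the parents by at least 1 on the log2 scale, each animal was placed on a scale from 0 (U. ornatus mean) to 1 (U. graciosus mean) by the median over genes. The 6 hybrids were tested against 0.5 by a two-sided exact sign-flip test. No paired analysis was possible because no animal was measured at both temperatures and no replicate letter occurs in more than 1 group.

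Before the data were examined, 40 gene lists were fixed, 25 of pathways and 15 of cell type markers. Of these, 38 had at least 5 tested members. The antioxidant list held 50 genes, of which 43 were tested. It was written from general knowledge, since the authors' own 40 antioxidant genes are not named in the sources used here, so the lists may differ. Members were counted with adjustment over all genes and with adjustment over the list alone. Lists were tested by camera in limma 3.58.1 (two-sided, log2 CPM with a prior count of 2, preset correlation of 0.01), adjusted over the 38 lists within each of 10 contrasts, 380 tests in all, and again with the correlation estimated. None of the 72 calls with the preset correlation held with an estimated correlation, and each such adjusted p stands beside its list or list group.

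The genes named in each contrast were set by a rule: among genes past the threshold with a symbol and a mean of at least 1 CPM (the count relative to the scaled library total), the 8 largest rises and 8 largest falls, or the 3 smallest p where none passed; up to 4 called members of each list by p; up to 10 antioxidant genes called over the list alone; a fixed set of antioxidant and heat shock genes whatever their p; and the 2 members of each cell type list with the highest mean CPM. Where a gene outside this rule is named, the text says that it was chosen after its values were seen. For genes with 0 counts in a group, folds are lower bounds against a floor of 3 counts over the group. With 1 to 3 counts, the ratio stands with its 95% counting interval.

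Alternatives tried were DESeq2 1.42.0 with its own size factors, RLE factors in edgeR, no low-count filter, a filter of at least 5 CPM in 3 libraries, a log2 threshold of 1, limma voom with quality weights, only the groups compared in the fit, 1 temperature at a time, fry in place of camera, and each library left out in turn. Leaving out animals X, T and O together was added after seeing the data. Chance was gauged by refitting splits of the same animals, 10 for the 3 against 3 comparisons and 50 elsewhere. The pipeline was tested on simulated data built from these libraries. For the heat effect in hybrids, with 3 animals a side, it recovered 12% of 2-fold and 64% of 4-fold changes, with 6 false calls among 82. For hybrids against U. graciosus, with 6 animals a side, it recovered 39% and 85%, with 7 false calls among 131.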

Results

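Liver transcripts were counted in 18 male lizards. There were 3 hybrids (Hy), 3 U. graciosus (Ug) and 3 U. ornatus (Uo) at 36 °C, and 3 other animals of each lineage at 40 °C. Totals ran from 15780346 counts in animal O to 35002548 in animal A. Replicates are named by the letters of their animals. The series asks whether antioxidant gene expression differs in hybrids, and its title names introgressed mitochondrial DNA and DNA damage from reactive oxygen species. Genes are identified by the symbols in the table.

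The livers separated by lineage first. Over the 15856 genes tested, the first principal component took 37.1% of the variance and parted U. ornatus from the other lineages, and the next took 13.1%. Median correlations of log2 CPM were 0.958 between hybrids, 0.958 within U. graciosus and 0.940 within U. ornatus. Between lineages they were 0.947 for hybrids with U. graciosus, 0.874 for hybrids with U. ornatus and 0.880 for the parents. Hybrid X at 40 °C stood apart on the next component, at a score of -142, against -49.6 for U. ornatus O and -18.0 for U. graciosus T. The TMM factors of X and O, 1.43 and 1.35, lay above those of the other libraries, and limma gave X, O and T quality weights of 0.160, 0.437 and 0.511.

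**Figure D1:**
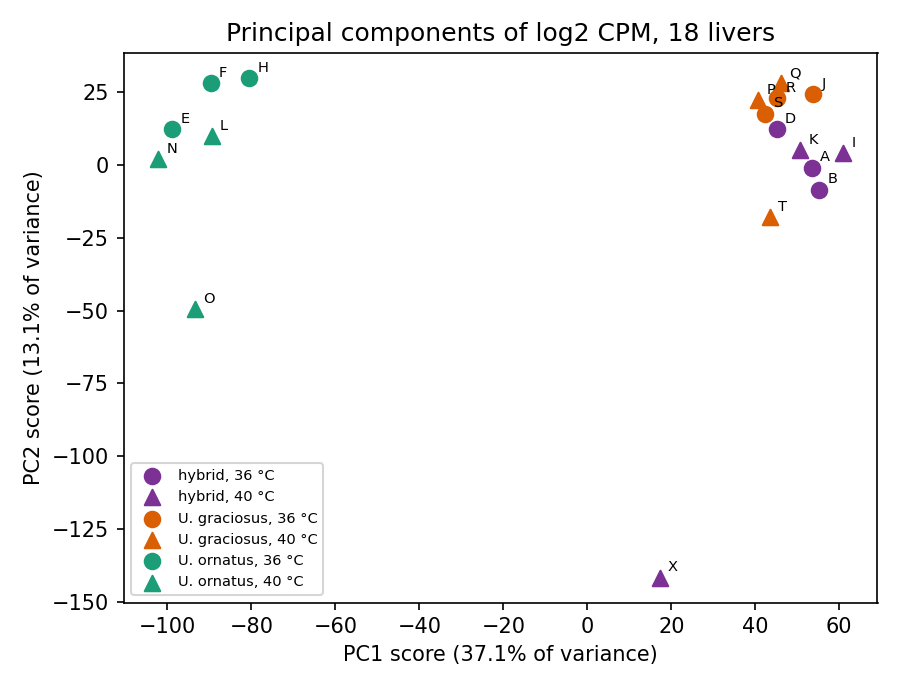
Scores of the 18 livers on the first principal component (x axis, 37.1% of the variance) and the next (y axis, 13.1%) of log2 CPM, 1 point per animal, coloured by lineage and shaped by temperature. U. ornatus lies apart from hybrids and U. graciosus along the x axis, and hybrid X lies at -142 on the y axis.

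The first comparison asks how liver expression differed between 40 °C and 36 °C across lineages. Genes of the heat shock response rose. HSP90AA1 and HSPH1, chaperones that refold or hold damaged proteins, rose by 2.64 ± 0.56 and 2.96 ± 0.61 on the log2 scale (SE, 9 animals against 9). HSPB6, a small heat shock protein, DNAJA4, a partner of the HSP70 chaperones, and SERPINH1, the collagen chaperone of the endoplasmic reticulum, rose by 4.77 ± 0.98, 3.73 ± 0.74 and 2.51 ± 0.53. GPAM, which starts triglyceride synthesis, fell by 0.74 ± 0.09, and SLC25A20, which carries acylcarnitines into mitochondria, fell by 0.89 ± 0.20.

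In all, 158 genes passed, 85 higher and 73 lower at 40 °C. The adjusted p was 0.0404 for HSP90AA1, HSPH1, HSPB6 and SERPINH1, 0.0339 for DNAJA4, 0.00609 for GPAM and 0.0493 for SLC25A20. Of the 9 animals at 40 °C, all 9 lay above every 36 °C animal of their own lineage for the 5 chaperones, all 9 lay below for GPAM and 8 for SLC25A20. The rise was uneven. HSP90AA1 stood at 207 to 386 CPM in the 9 animals at 36 °C. At 40 °C it stood at 403, 417 and 1694 CPM in hybrids I, K and X, at 589, 570 and 10847 CPM in U. graciosus P, Q and T, and at 627, 626 and 2467 CPM in U. ornatus L, N and O. Without X, T and O (an alternative chosen after seeing the data), HSP90AA1 rose by 1.04 ± 0.15 (adjusted p = 0.0165), HSPB6 by 1.31 ± 0.21 (0.0249) and DNAJA4 by 1.51 ± 0.27 (0.0381), while HSPH1, at 1.20, and SERPINH1, at 1.12, had adjusted p of 0.0529 and 0.0708. These animals were left out for their high values of the same genes, which narrows the spread. Adjusted p of heat shock genes and of their list without X, T and O are therefore descriptive only. HSPA8, the constitutive HSP70, and DNAJB1, a heat-inducible HSP40, did not pass with all animals (2.52 ± 0.64 and 1.96 ± 0.57, adjusted p = 0.0700 and 0.109, above in 8 and 7 of 9 animals). HSF1, the transcription factor of the response, was at 0.09 ± 0.11 (0.720) and HSPB1, another small heat shock protein, at -0.23 ± 0.42 (0.815).

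**Figure D2:**
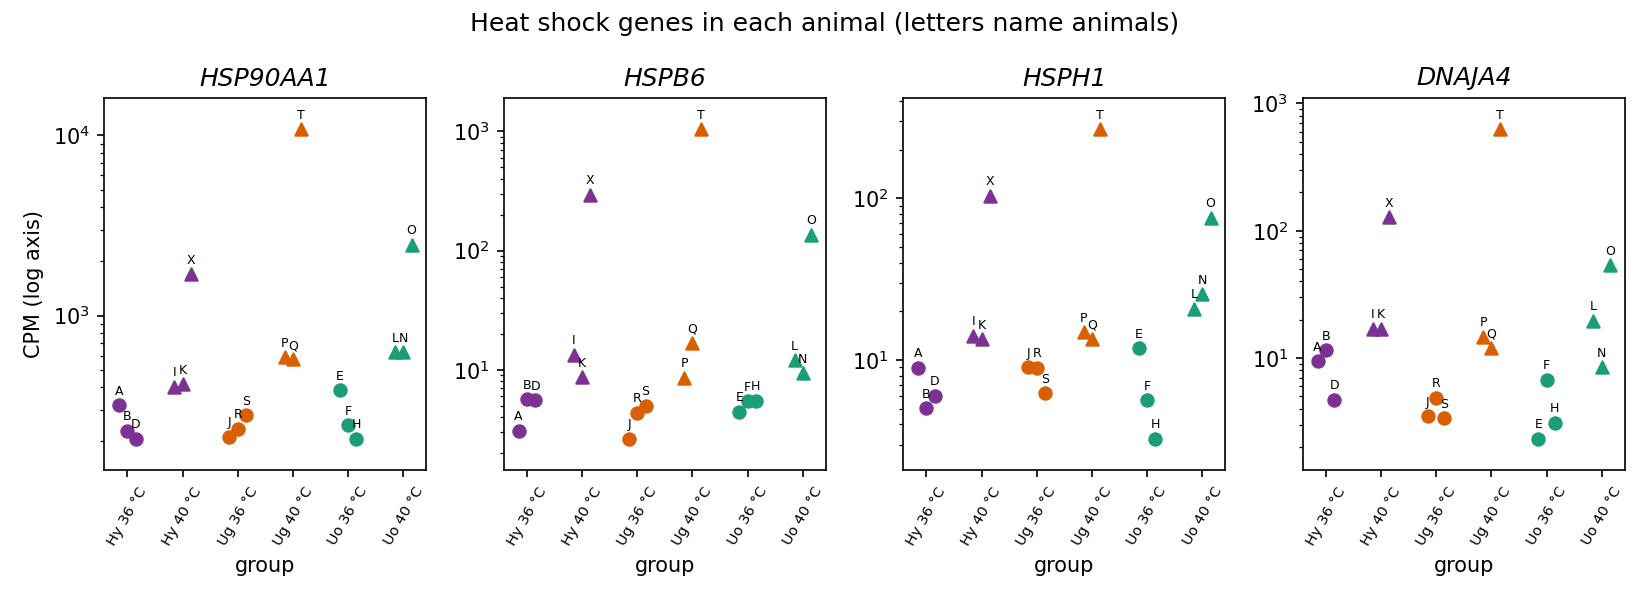
CPM (log axis) of heat shock genes in each of the 18 animals by lineage and temperature, 1 letter per animal. In each lineage 1 animal at 40 °C (X, T or O) lies above its companions, with HSP90AA1 at 1694, 10847 and 2467 CPM.

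The other large rises were AMH, a hormone of the gonad, by 1.72 ± 0.28 (adjusted p = 0.0200, 9 of 9 animals), GABRR3, a GABA receptor subunit, by 2.41 ± 0.40 (0.0200, 8 of 9), AKAP5, an anchor for protein kinase A, by 3.06 ± 0.62 (0.0404, 8 of 9), and LEMD1 by 2.95 ± 0.49 (0.0266, 7 of 9 above and 2 below every 36 °C animal of their lineage). AKAP5 rested on few counts outside U. ornatus, 4 in the hybrids and 38 in U. graciosus at 40 °C. LEMD1 had 0 counts in U. ornatus at 36 °C and 56 at 40 °C. ENDOG, a mitochondrial nuclease, rose by 0.64 ± 0.15 (0.0493, 8 of 9). The largest falls were CATSPER3, a sperm calcium channel subunit (-3.68 ± 0.71, 0.0285, 6 of 9), TMEM61 (-3.48 ± 0.61, 0.0266, 8 of 9), IQANK1 (-2.64 ± 0.48, 0.0285, 7 of 9 below and 1 above) and SLC15A2, a peptide transporter (-2.47 ± 0.44, 0.0266, 9 of 9). In U. ornatus IQANK1 went from 12 counts to 0 and TMEM61 from 227 to 2. The fitted values of AKAP5, LEMD1, IQANK1 and TMEM61 depend on the prior count, as each had a group at 2 counts or fewer. SFMBT2, EPS8L3, GCA and SLC12A5 fell by between 1.34 and 1.44.

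By list, 34 of 43 cytosolic heat shock genes lay above 0 (median 0.43, mean 0.89), and the list rose (adjusted p = 5.53e-05; adjusted p = 0.729 with an estimated correlation). Its median was 0.12 (0.00504) without X, T and O. Of its members 5 rose over all genes; adjusted over the list alone, 17 rose and 2 fell, HSF2 and BAG1, both chosen after their values were seen. The ER stress list had a median of 0.44 with 28 of 32 members above 0 (adjusted p = 0.0156; adjusted p = 0.897 with an estimated correlation), and without X, T and O its median was -0.12 (0.725). Hepatocyte markers fell as a list (median -0.45, 2 of 18 above 0, 0.000638), as did acute phase proteins (-0.37, 5 of 22, 0.00353), amino acid catabolism (-0.25, 3 of 22, 0.00503), endothelial markers (-0.27, 4 of 18, 0.0116) and skeletal muscle genes (-1.20, 1 of 13, 0.0113), each without a member past the threshold over all genes. With an estimated correlation, the adjusted p was 0.729 for these lists except acute phase (adjusted p = 0.877). Adjusted over the list alone, 1 endothelial gene fell. The kidney and gonad list rose (1.20, 6 of 8, 0.0116; adjusted p = 0.503 with an estimated correlation), with AMH called over all genes and 3 members adjusted over the list alone, AMH and, chosen after their values were seen, STAR and SLC12A3. Its median was 0.59 (0.0483) without X, T and O. Amino acid catabolism lost its call without X, T and O (adjusted p = 0.205) or without X alone (0.05005), endothelial markers without Uo_36 H (0.0589), and skeletal muscle without hybrid D (0.150). ER stress lost it without H (0.0694), O (0.215), D (0.151), X (0.105), J (0.107) or T (0.196).

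The count of 158 rested on small margins. It was 131 without X, within 1.5 times of 158 without Ug_36 J as well, and lower without any other animal. In U. ornatus it was 65, 14 and 100 without E, F and H at 36 °C and 98, 99 and 9 without L, N and O at 40 °C. Among hybrids it was 43, 25 and 30 without A, B and D and 94 and 85 without I and K. In U. graciosus it was 6 and 13 without R and S at 36 °C and 69, 82 and 53 without P, Q and T at 40 °C. GPAM passed in all 18 leave-outs (highest adjusted p 0.0258), while HSP90AA1, HSPB6 and HSPH1 passed in 6 and DNAJA4 and SERPINH1 in 7, with highest adjusted p of 0.0918, 0.0931, 0.0931, 0.0854 and 0.0931. Without X, T and O, 55 genes passed, 43 of them among the 158.

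No antioxidant enzyme passed the test of the mean heat effect. Superoxide dismutases SOD1 (cytosolic) and SOD2 (mitochondrial) were at -0.02 ± 0.19 and -0.17 ± 0.14, catalase (CAT), which removes hydrogen peroxide, at -0.19 ± 0.29, and the glutathione peroxidases GPX1 and GPX4 at 0.06 ± 0.23 and -0.25 ± 0.19. The mitochondrial peroxiredoxin PRDX3 was at -0.44 ± 0.22. Their adjusted p were 0.979, 0.541, 0.766, 0.920, 0.526 and 0.309. In edgeR 0 of 43 passed, over all genes or adjusted over the list alone, with 9 at an unadjusted p under 0.05, 2 in DESeq2 and 1 in voom. The list as a set was not called (adjusted p = 0.157, 17 of 43 above 0). The count adjusted over the list alone was 1 without Uo_36 E, 2 without Uo_36 H and 1 without Hy_36 D.

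Within hybrids, the comparison asks how liver expression differed between 40 °C and 36 °C in the cross itself. Chaperone, proteasome and mitochondrial genes lay higher as lists at 40 °C, and muscle, B cell and hepatocyte genes lay lower, each called only with the preset correlation (adjusted p of 0.274 to 0.549 with an estimated correlation). Without X the heat shock (0.428), proteasome (0.325) and hepatocyte (0.287) lists were not called. The skeletal muscle list fell (median -2.38, 0 of 13 above 0, adjusted p = 8.25e-10; adjusted p = 0.274 with an estimated correlation), with ATP2A1, the calcium pump of muscle, at -8.00 ± 1.70 (883 counts over 3 animals at 36 °C and 4 at 40 °C), while at 36 °C hybrid D held 22.5 CPM of ACTA1 and 31.7 of CKM, both muscle proteins chosen after their values were seen, and hybrid B held 7.70 and 4.19, against 0.774 and 0 in A. The proteasome, which degrades tagged proteins, rose as a list (0.28, 31 of 32, 0.000207), and so did cytosolic heat shock genes (0.58, 34 of 43, 0.000309), with adjusted p = 0.527 and adjusted p = 0.485 with an estimated correlation. Nuclear genes of OXPHOS complex I and of complexes II to V, the respiratory chain, rose as lists (0.18, 32 of 36, 0.00557, and 0.29, 16 of 18, 0.00285), as did the mitochondrial ribosome (0.22, 61 of 77, 0.000353), with adjusted p = 0.549 for complex I and adjusted p = 0.485 for the others with an estimated correlation. Without X, T and O the median was 0.08 (0.0835) for heat shock and 0.27 (7.58e-07) for complex I.

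No single gene passed in edgeR (0 genes, 1239 at an unadjusted p under 0.05, 55 in DESeq2 and 0 in voom), and 0 passed in each leave-out. The smallest p belonged to FES, a tyrosine kinase of blood cells (-2.14 ± 0.43), ATP2A1 and RPS6KA2, a kinase of growth signalling (2.18 ± 0.47), each with an adjusted p of 0.546 in 3 of 3 animals. HSP90AA1 was at 1.73 ± 0.93 (0.677) and HSPH1 at 2.71 ± 1.05 (0.580). Adjusted over the list alone, 6 muscle genes, 2 of B and plasma cells and 2 of fatty acid synthesis fell, and of gluconeogenesis 2 rose and 1 fell.

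The other lists called in hybrids were cell cycle (median 1.78, 33 of 35 above 0, adjusted p = 0.00063), stellate cell and fibroblast (0.86, 17 of 19, 0.000309), ER stress (0.36, 25 of 32, 0.0437) and cytosolic ribosome (0.13, 53 of 68, 0.0166), all higher. With an estimated correlation none was called: adjusted p = 0.549 for cell cycle, 0.485 for stellate cell, 0.664 for ER stress and 0.711 for the ribosome. Lower were hepatocyte (-0.57, 1 of 18, 2.36e-05), B and plasma cell (-0.75, 0 of 11, 0.00061), erythrocyte (-0.69, 3 of 12, 0.00248), circadian clock (-0.32, 4 of 17, 0.00962), amino acid catabolism (-0.21, 5 of 22, 0.0145), fatty acid and triglyceride synthesis (-0.47, 8 of 19, 0.0175), acute phase (-0.16, 7 of 22, 0.0184), T and NK cell (-0.77, 0 of 13, 0.0281), gluconeogenesis (-0.34, 8 of 20, 0.0344, with a mean of 0.29 in the opposite direction) and iron handling (-0.12, 5 of 15, 0.0457). Each of these lost its call with an estimated correlation: adjusted p = 0.469 for fatty acid synthesis, 0.5001 for amino acid catabolism, 0.563 for T and NK cell, 0.570 for acute phase, and 0.485 for hepatocyte, B and plasma cell, erythrocyte, clock, gluconeogenesis and iron. Animal X carried much of this. Without X, the adjusted p was 0.428 for heat shock, 0.325 for the proteasome, 0.287 for hepatocyte, 0.893 for stellate cell, 0.734 for ER stress, 0.734 for amino acid catabolism, 0.682 for the clock, 0.498 for iron, 0.428 for erythrocyte, 0.289 for T and NK cell and 0.287 for gluconeogenesis, and cell cycle and acute phase lay the other way (0.0794 and 0.242). Complex I lost its call without A (0.131), I (0.0989) or K (0.224), complexes II to V without A (0.0567), D (0.119) or K (0.0659), fatty acid synthesis without A (0.130), I (0.0564) or K (0.130), the ribosome without B (0.0562), I (0.0579) or K (0.400), and B and plasma cell without D (0.0951). Some calls were also lost without another animal. These were cell cycle without B (0.0757), amino acid catabolism without B (0.360), the clock without D (0.208), acute phase without A (0.119) or B (0.115), gluconeogenesis without B (0.115), D (0.122) or I (0.0564), and T and NK cell without A (0.165), D (0.442) or I (0.431). They included iron without A (0.131), B (0.0580), I (0.0579) or Ug_40 T (0.0550), and ER stress without Uo_36 E (0.0518), A (0.0582) or I (0.127) and, lying the other way, without D (0.949). The mitochondrial ribosome and skeletal muscle lists stayed called in all 18 leave-outs.

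In U. graciosus, heat shock genes again lay higher at 40 °C, along with complex I, while macrophage and endothelial markers lay lower, none of them called with an estimated correlation (adjusted p = 0.614 for endothelial markers, adjusted p = 0.955 for the others). The heat shock list rose (median 0.53, 37 of 43 above 0, adjusted p = 9.91e-07), with 16 members higher adjusted over the list alone, where 1 macrophage gene was lower. HSP90AA1 was at 4.04 ± 1.03 (adjusted p = 0.526) and DNAJB1 at 4.17 ± 1.08, neither past the test. DNAJB1 stood at 2196 CPM in T, against 59.1 in P and 57.8 in Q and 39.6 to 45.2 at 36 °C. Without T the heat shock list had an adjusted p of 0.0485, and without X, T and O its median was 0.17 (0.00199), that of complex I 0.37 (4.15e-10) and that of endothelial markers -0.56 (2.86e-06). ER stress (0.62, 27 of 32, 0.00205) and complex I (0.22, 32 of 36, 0.000849) rose, and endothelial (-0.31, 1 of 18, 0.000849) and macrophage markers (-0.54, 2 of 13, 0.000849) fell. With an estimated correlation the lists were not called (adjusted p = 0.614 for endothelial markers and adjusted p = 0.955 for the other 4). ER stress lost its call without J (0.189) or T (0.894), complex I without P (0.164) or Q (0.106), and endothelial markers without Q (0.0592). In edgeR 0 genes passed, with 968 at an unadjusted p under 0.05, 38 in DESeq2 and 1 in voom. The smallest p belonged to GABRR3 (4.34 ± 0.78), TMCO6 (-1.005 ± 0.19) and MTG1, a GTPase of mitochondrial ribosome assembly (-0.93 ± 0.18), each with an adjusted p of 0.433 in 3 of 3 animals.

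In U. ornatus single genes passed as well. TRIM24, a co-regulator of nuclear receptors, rose by 2.03 ± 0.26, LRFN5, a neural adhesion protein, by 2.52 ± 0.39, ABCB9, a peptide transporter of lysosomes, by 2.53 ± 0.42, and JCHAIN, the joining chain of antibodies, by 2.72 ± 0.51. The muscle channels SCN4A and RYR1 rose by 3.00 ± 0.59 and 2.20 ± 0.49. GPAM fell by 1.42 ± 0.17 and SLC15A2 by 5.05 ± 0.88. A pair of DNA repair genes fell, NBN of the double-strand break sensor by 0.87 ± 0.17 and XRCC5 of end joining by 0.79 ± 0.17.

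In all, 124 genes passed, 61 higher and 63 lower. The adjusted p were 0.00647 for TRIM24, 0.0205 for LRFN5, 0.0261 for ABCB9, 0.0285 for JCHAIN, 0.0383 for SCN4A, 0.0499 for RYR1, 0.00388 for GPAM, 0.0281 for SLC15A2, 0.0365 for NBN and 0.0494 for XRCC5, each in 3 of 3 animals. CATSPER3 fell from 1250 to 6 counts over 3 animals and TMEM61 from 227 to 2. LEMD1 rose from 0 to 56, and PITPNM3 rose, while WEE2, RMI1, TMC4, EPS8L3 and ZBTB20 fell by between 2.41 and 4.18. Acute phase proteins fell as a list (median -0.83, 5 of 22 above 0, adjusted p = 0.00387), as did the proteasome (-0.30, 7 of 32, 0.0225) and hepatocyte markers (-0.58, 2 of 18, 0.0479), each with adjusted p = 0.979 with an estimated correlation. Adjusted over the list alone, 1 acute phase gene fell. The proteasome lost its call without E (0.300), L (0.0840) or N (0.133), and hepatocyte markers without F (0.151), H (0.0542), N (0.0863), O (0.110), Ug_36 R (0.0539), Ug_36 S (0.0504) or X, T and O together (0.0535). The count of 124 became 0 when only the U. ornatus libraries entered the fit, 305 without hybrid X, and lower without E (31), F (5), H (43), L (45), N (49), O (6), A (35), B (68), D (52), I (59), K (66), J (69), P (39), Q (42) or R (43), staying within 1.5 times only without Ug_36 S and Ug_40 T. GPAM and TRIM24 passed in all 18 leave-outs, SLC15A2 and ABCB9 in 15, LRFN5 in 17, JCHAIN in 12, SCN4A in 9, NBN in 7, XRCC5 in 3 and RYR1 in 1.

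Among antioxidant genes, the peroxiredoxins PRDX4 of the endoplasmic reticulum (-1.50 ± 0.34) and PRDX6, which also reduces oxidised phospholipids (-0.91 ± 0.25), fell in U. ornatus adjusted over the list alone (adjusted p = 0.0219 and 0.0499, 3 of 3 animals), and 0 of 43 passed over all genes in edgeR (0.0557 and 0.101), with 10 at an unadjusted p under 0.05, 5 in DESeq2 and 3 in voom. SOD2 was at -0.79 (0.124) and PRDX3 at -1.09 (0.178). In hybrids 0 passed (4 at an unadjusted p under 0.05, 1 in DESeq2, 1 in voom), as in U. graciosus (1, 0 and 1). As a set the list was not called in U. ornatus (adjusted p = 0.0644), hybrids (0.937) or U. graciosus (0.727). The 2 in U. ornatus became 0 without F, L, N or O, without X, T and O together, or when only U. ornatus entered the fit, 1 without I, K, P, Q, R or T, 4 without E and 5 without X. The 0 in hybrids became 1 without Uo_36 F, Uo_40 N or D, 2 without I and 3 without K.

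The differences of heat effects ask whether lineages responded unlike each other. TPP1, a lysosomal peptidase, stood at 2374 counts at 36 °C and 1948 at 40 °C over the 3 hybrids of each, at 1559 and 846 in U. graciosus and at 496 and 1420 in U. ornatus. Its heat effect was lower in U. graciosus than in U. ornatus by 1.91 ± 0.25 on the log2 scale (adjusted p = 0.0216), and it was the 1 gene in the test of any difference (0.0438). LRFN5 and TRIM24 followed for hybrids against U. ornatus at -3.19 ± 0.51 (0.0717) and -2.13 ± 0.36 (0.0869), with TPP1 at -1.58 ± 0.25 (0.0717). For hybrids against U. graciosus the smallest p belonged to MYLPF, a muscle light chain (-6.68), PIK3R1, a regulator of insulin signalling (-2.07), and ANKRD9 (-3.17), each at an adjusted p of 1.

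In edgeR 0 genes passed for hybrids against U. graciosus (545 at an unadjusted p under 0.05, 3 in DESeq2, 0 in voom) and 0 for hybrids against U. ornatus (1529, 93 and 1). For the parents 1 passed (1183, 66 and 6), and 1 in the test of any difference (1127, 80 and 6). The parents' count was 0 without F, O, A, I, J, P, R or S, 2 without E or T and 3 without L or N, and 0 without X, T and O. TPP1 itself lost its call without F (0.141), H (0.0632), O (0.0703), A (0.0523), I (0.0505), J (0.101), P (0.0510), Q (0.0759), R (0.0862) or S (0.0740). The test of any difference gave 0 genes without E, F, N, O, A, D, I, J, P, R, S or T and 2 without L or X. Hybrids against U. ornatus had 1 gene without Uo_40 L, I, X or Q and 2 without Uo_36 H or T. Across genes, which are not independent replicates, heat effects of lineage pairs correlated at r of 0.147 to 0.169 and rho of 0.179 to 0.235, and 57.3% to 59.6% shared a sign. Of the 124 genes called in U. ornatus, 75 had that sign in hybrids and 90 in U. graciosus.

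The lineage comparisons bear on whether hybrids resemble a parent. Against U. graciosus, hybrids had higher cell cycle genes as a list (adjusted p = 6.75e-10; adjusted p = 0.88 with an estimated correlation), most of all in X with a mean log2 CPM of 4.68, and 4 lower interferon genes. STAT2, which relays interferon signals, stood at 28.8 CPM in hybrids against 113 in U. graciosus (log2 -1.89 ± 0.23, n = 6 and 6), beside 27.0 in U. ornatus. ISG15, an interferon-induced modifier, was also lower (-2.72 ± 0.41), as were DDX58, a sensor of viral RNA (-1.44 ± 0.35), and IRF8, a factor of myeloid cells (-1.45 ± 0.34). FOXO1, a regulator of glucose production, was higher by 1.13 ± 0.23. The mitochondrial ribosome gene MRPL17 was lower (-1.49 ± 0.28).

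In all, 288 genes passed, 129 higher and 159 lower in hybrids. The adjusted p was 0.000776 for STAT2, 0.00276 for ISG15, 0.0463 for DDX58, 0.0427 for IRF8, 0.0181 for FOXO1 and 0.011 for MRPL17. Of 6 hybrids, 6 lay below all 6 U. graciosus for STAT2 and MRPL17, 4 for ISG15, 2 for DDX58 and 1 for IRF8, and 6 lay above for FOXO1. The interferon list had 4 called members, all lower, and was not called as a set (adjusted p = 0.103). The largest rises included LPAR3, a lysophospholipid receptor, at 7.30 ± 1.22 (3.36 against 0.041 CPM, 0.00771, 5 of 6), TMEM233 at 6.74 ± 0.73, IL1RAPL1, a synaptic receptor, at 6.66 ± 0.86, CDHR3, an epithelial cadherin, at 6.16 ± 1.21, HPDL, a mitochondrial dioxygenase, at 3.95 ± 0.44 (0.000339, 6 of 6), and PLA2R1 at 3.81 ± 0.64, with VSTM2L (3.99) and SLC4A3 (3.67). The largest falls included COL7A1, an anchoring collagen of epithelia, at -5.35 ± 0.81 (0.613 against 21.3 CPM, 0.00276, 6 of 6), IQSEC3 at -4.45 ± 0.69 (8.71 against 194 CPM, 0.0033, 6 of 6) and GALNT14, a glycosyltransferase, at -4.25 ± 0.51 (0.00072, 6 of 6), with AGBL3 (-6.04), SPRED3 (-5.19), SH3GL2 (-5.03), RBM44 (-4.30) and TNFSF14 (-4.08, with 0 of 6 hybrids below all U. graciosus). GGT7, of the glutathione transferase list, was higher by 3.65 ± 0.85 (94.2 against 11.5 CPM, 0.0425, 4 of 6), CLDN3 by 2.74 ± 0.59 (4 of 6) and FECH, the last enzyme of haem synthesis, by 0.996 ± 0.24 (0.0454, 5 of 6).

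Of 35 cell cycle genes, 34 lay above 0 (median 1.93) and the list was higher in hybrids (adjusted p = 6.75e-10; adjusted p = 0.88 with an estimated correlation), with KIF11, a spindle motor, called over all genes (2.70 ± 0.65, 0.0467, 3 of 6) and 26 members adjusted over the list alone. The mean log2 CPM of the list stood at 4.68 in X and 2.01 in T, the highest of their lineages. Hybrids were uneven in MKI67 and TOP2A, both chosen after their values were seen. MKI67 stood at 1.72 CPM in B and 0.752 in I, below the 2.58 to 6.53 of U. graciosus. It stood at 13.6, 10.2, 5.78 and 81.2 in A, D, K and X. TOP2A in B and I (2.36 and 2.17 CPM) lay within the 1.16 to 7.60 of U. graciosus. The list stayed called in all 18 leave-outs, with a highest adjusted p of 9.61e-06 without X, and its median was 1.20 (5.72e-12) without X, T and O. Ribosomal proteins (0.16, 60 of 68, 0.000167), complex I (0.17, 30 of 36, 0.00123), complexes II to V (0.28, 17 of 18, 0.00328), gut and gallbladder epithelium (1.36, 7 of 7, 0.004) and macrophage markers (0.45, 11 of 13, 0.0348) were higher as lists, and acute phase proteins lower (-0.35, 3 of 22, 0.0153). With an estimated correlation, adjusted p = 0.146 for gut and gallbladder and adjusted p = 0.88 for the others. Adjusted over the list alone, 1 macrophage and 1 gut gene were higher. Without T, calls were lost for the ribosome (0.184), complex I (0.0874), complexes II to V (0.0589), acute phase (0.151) and macrophages (0.0841). Acute phase was also lost without D (0.0927), X (0.577) or S (0.0669), and macrophages without A (0.0524), D (0.167), K (0.0567), X (0.120), J (0.0975) or Q (0.0594). The count of 288 fell to 135 without A, 175 without B, 158 without P, 174 without Q, 151 without R and 152 without S, with 281 at most without K. STAT2, ISG15 and MRPL17 passed in all 18 leave-outs, FOXO1 in 17, GGT7 in 6, KIF11 and FECH in 5, DDX58 in 3 and IRF8 in 2.

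The study's question concerns antioxidant genes, which are compared here between hybrids and U. graciosus. PRDX2, an abundant cytosolic peroxiredoxin (1.16 ± 0.32, 50.2 against 22.6 CPM, 6 of 6 animals), and PRDX6 (0.63 ± 0.18, 3 of 6) were higher, and SOD3, the extracellular superoxide dismutase, was lower (-1.06 ± 0.30, 5 of 6), each only adjusted over the list alone (adjusted p = 0.0396), against 0.0855, 0.0889 and 0.0911 over all genes. In edgeR 0 of 43 passed over all genes, with 9 at an unadjusted p under 0.05; adjusted over the list alone, DESeq2 gave 4 and voom 7. The list as a set was not called (0.0852). SOD2 was at 0.38 and GPX1 at 0.78 (0.185). The count of 3 held without Uo_36 E or X, was 1 without A, J or S, and was 0 without any other animal, in the fit of the 2 lineages alone, and without X, T and O.

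Against U. ornatus, hybrids showed broad differences, and reads of both were aligned to another genus, so these include any difference in alignment. Among antioxidant genes, SOD3 was lower in hybrids (log2 -3.28 ± 0.32, 43.5 against 421 CPM, 6 of 6 animals, adjusted p = 4.99e-06) and so was NQO1, a quinone reductase (-2.52 ± 0.32, 1.31 against 7.79 CPM, 6 of 6, 4.61e-05). PRDX5, a peroxiredoxin of mitochondria and peroxisomes, was higher by 1.02 ± 0.16 (82.5 against 40.7 CPM, 6 of 6, 0.000233), OXR1, which guards against oxidation, by 1.14 ± 0.23 (4 of 6, 0.00172), SOD2 by 0.74 ± 0.17 (3 of 6, 0.00365), MSRB3, a repair enzyme of oxidised methionine, by 1.55 ± 0.38 (6 of 6, 0.00568) and GPX4, which reduces lipid peroxides, by 0.70 ± 0.24 (5 of 6, 0.031).

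In all, 16 of 43 antioxidant genes passed, 8 higher and 8 lower, over all genes and adjusted over the list alone. This share was close to that over all genes, where 5580 of 15856 passed. PRDX6 and, chosen after their values were seen, GCLM and GLRX5 were also higher, and BLVRA, HMOX1 and GLRX3 were lower, as were SESN3, TXNRD1 and CCS, likewise chosen after. SOD1 was at 0.44 (0.141), CAT at 0.72 (0.132), GPX1 at 0.67 (0.0796) and PRDX3 at 0.50 (0.164). The list as a set was not called (0.981). The count of 16 was 10 without E, 9 without L, 9 without A, 8 without K and 25 without X. Over all genes 5580 passed, 2893 higher and 2687 lower. HSF1 was higher by 1.56 ± 0.14 (27.7 against 9.42 CPM, 6 of 6, 3.12e-06), with 19.5 CPM in U. graciosus. Complex I was higher as a list (median 0.38, 25 of 36 above 0, 0.00576; adjusted p = 0.963 with an estimated correlation), with 14 members called, or 16 adjusted over the list alone, such as NDUFB10 (1.495 ± 0.20, 125 against 44.5 CPM) and NDUFS6 (1.71). Complexes II to V were higher (0.53, 18 of 18, 0.00576), 9 of them called either way, such as ATP5F1A (0.86), and so were stellate cell and fibroblast markers (1.43, 16 of 19, 0.00304), 14 higher and 1 lower over all genes and 15 and 1 adjusted over the list alone, such as PDGFRA (2.32 ± 0.30) and TAGLN (3.08 ± 0.44). The latter lists too had an adjusted p = 0.963 with an estimated correlation. Of DNA damage genes 1 was higher, NBN (1.01 ± 0.12, 2.71e-05), and 11 were lower, among them ATM, the kinase that signals breaks (-1.14 ± 0.11, 5e-06), RAD50 (-1.20) and FAS (-3.19), and the list was not called. Of base excision repair genes 5 were higher and 3 lower, among them the glycosylases MPG (1.23) and NTHL1 (1.29) and the ligase LIG3 (-0.76). With 37 DNA damage and 26 base excision repair genes tested, these shares were no higher than that over all genes. The largest rises were ACBD7 (8.39 ± 0.77), GGT7 (8.36 ± 1.12), SH2D4B, ELAPOR2, SLC24A2, CALML4, PSD and SYT11, each above in 6 of 6 animals. CACNA2D3 was at least 994-fold lower, TCFL5 at least 1186-fold, AVPR1B at least 323-fold and CCDC33 at least 302-fold, the last with 0 of 6 animals below all U. ornatus. L3MBTL1 (-9.48), SLC16A4 (-8.70 ± 0.63), ATP6V1B1 (-8.64) and DNAH5 (-8.49 ± 0.50) followed.

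**Figure D3:**
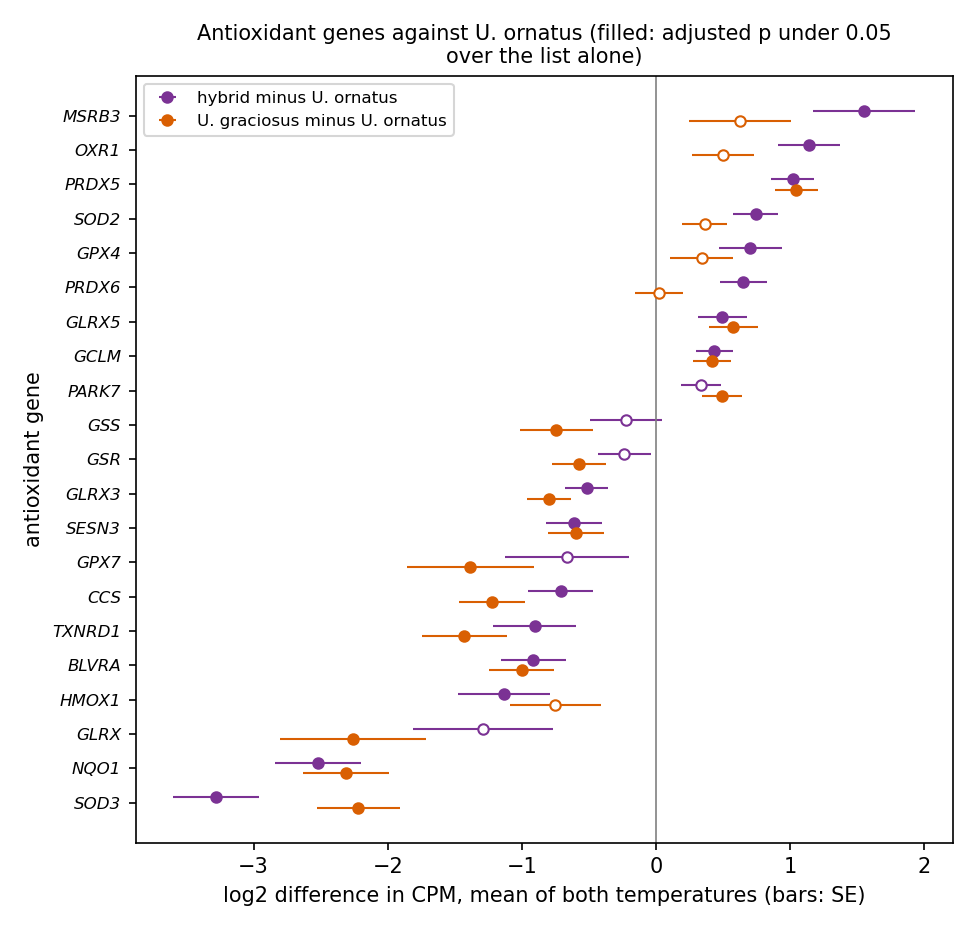
Log2 difference in CPM from U. ornatus (x axis, mean over both temperatures, bars are SE) for antioxidant genes (y axis) in hybrids and U. graciosus, 6 animals per lineage. Filled points passed adjusted over the list alone, and SOD3 lies at -3.28 in hybrids and -2.22 in U. graciosus.

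The parents, the reference for placing the hybrids, differed in antioxidant, immune and many other genes, again including any difference in alignment. NQO1 (log2 -2.31 ± 0.32, adjusted p = 0.000106) and SOD3 (-2.22 ± 0.31, 0.000113) were lower in U. graciosus, and PRDX5 was higher by 1.05 ± 0.16 (0.000223), each in 6 of 6 animals. TXNRD1, the thioredoxin reductase of the cytosol, was lower (-1.43 ± 0.31, 0.00311, 6 of 6). T cell genes such as LCK (-2.33), SKAP1 (-3.53), TBX21 (-3.52) and CD28 (-4.78) and the macrophage genes CTSS (-2.16), VSIG4 (-2.12), C1QA (-1.03) and C1QB (-1.22) were lower in U. graciosus. The interferon genes STAT2 (1.98 ± 0.23, 2.64e-05, 6 of 6), IRF7 (2.14, 6 of 6) and DDX58 (1.77, 5 of 6) were higher, and TLR4, a receptor for bacterial lipids, was lower (-1.70).

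Of 43 antioxidant genes, 15 passed, 4 higher and 11 lower, over all genes and adjusted over the list alone, and the list as a set was not called (0.39). Over all genes a similar share passed, 5100 of 15856. CCS, GLRX3, GLRX and BLVRA were the other falls and PARK7 and GLRX5 the other rises, along with GPX7, GSR, SESN3 and GSS (lower) and GCLM (higher), chosen after their values were seen. The count was 8 without R and 17 at most, without X. Over all genes 5100 passed, 2541 higher and 2559 lower. Macrophage markers were lower as a list (median -1.02, 0 of 13 above 0, 0.00942, 9 called either way), as were T and NK cell markers (-2.09, 1 of 13, 0.0159, 7 called either way), which lost the call without Uo_36 E (0.0661) or Uo_40 N (0.0552). Both had an adjusted p = 0.929 with an estimated correlation. Stellate cell and fibroblast markers were higher (1.20, 16 of 19, 0.00942), with 8 higher and 1 lower, or 10 and 1 adjusted over the list alone (adjusted p = 0.929 with an estimated correlation). DNA damage genes went both ways, 4 higher and 9 lower, with BRCA1 (-1.89 ± 0.35) and CHEK1 (-1.82) of replication repair among the falls and NBN (1.04) among the rises. With 37 DNA damage genes tested, this share was close to that over all genes, and the list was not called. The largest rises were EPSTI1 (8.86 ± 1.16), SYT2 (a ratio of 657, interval 181 to 5430, 4 of 6 animals), CALML4 (8.26 ± 0.47), SLC24A2, SH2D4B, EYA4, ELAPOR2 and LRRC63. The largest falls were FAIM2 (at least 228-fold), AVPR1B (a ratio of 822, interval 147 to 32487), AMELX (555, interval 99.3 to 21970), DNAH5 (-8.79 ± 0.51), ETNK2, KCNA7, SLC16A4 and TCFL5.

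Over many genes, hybrids lay nearer to U. graciosus than to U. ornatus. Over the 3045 genes that parted the parents, hybrids had a mean position of 0.919 ± 0.102 (SD, n = 6), where 0 is U. ornatus and 1 is U. graciosus. Animals A, B, D, I, K and X lay at 0.936, 0.980, 0.930, 1, 0.949 and 0.719. The mean differed from 0.5 (exact sign-flip test, two-sided p = 0.0313, the smallest that 6 animals allow). U. graciosus animals lay at 1.006 ± 0.0135 and U. ornatus at -0.002 ± 0.0646 by construction. A gene with 0 counts both in an animal and in U. graciosus scores exactly 1, the median of hybrid I and of U. graciosus Q and R. Reads were aligned to another genus, so the position describes counted reads and includes any likeness in alignment.

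**Figure D4:**
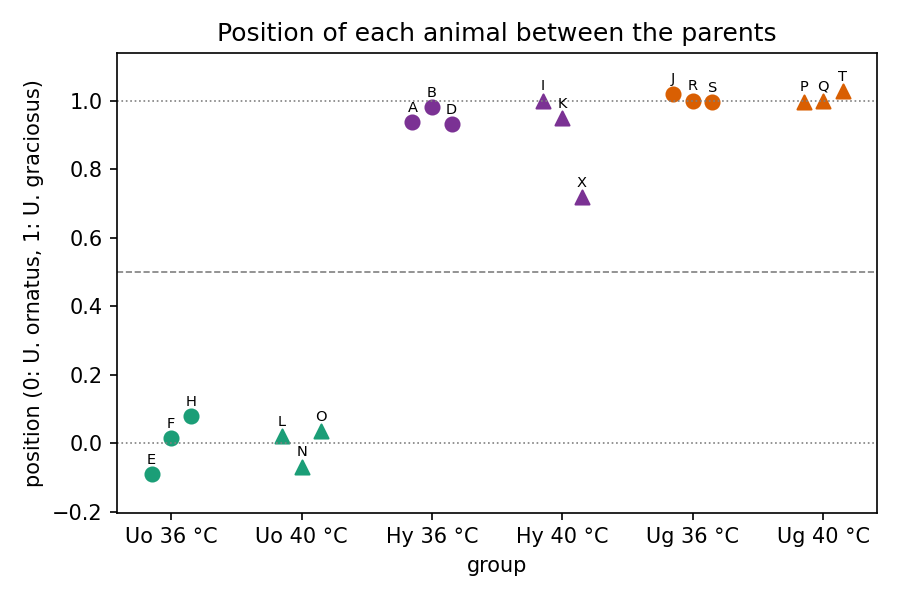
Position of each animal (y axis, no unit) between the mean of U. ornatus (0) and of U. graciosus (1), the median over 3045 genes, by group (x axis). The 6 hybrids lie between 0.719 (X) and 1 (I), all above 0.5.

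Some genes in hybrids lay beyond both parents, which asks whether hybrids differ from a mixture of them. HPDL was higher than in U. graciosus by 3.95 ± 0.44 and than in U. ornatus by 5.81, IL1RAPL1 by 6.66 ± 0.86 and 6.78, and LPAR3 by 7.30 ± 1.22 and 6.63. GGT7, FECH, PLA2R1, TMEM233, CLDN3 and SLC4A3 were also higher than in both. GALNT14 (-4.25 ± 0.51 and -4.98) and COL7A1 (-5.35 ± 0.81 and -2.36) were lower than in both, with AGBL3, RBM44, SH3GL2 and IRF8. In all there were 162 such genes, 76 higher and 86 lower, and 66 of them carried placeholder names. The adjusted p against U. ornatus was 1.57e-06 for HPDL, 0.000139 for IL1RAPL1, 0.000583 for LPAR3, 1.03e-05 for GALNT14 and 0.0236 for COL7A1. If differences from each parent fell independently, 23.5 and 26.9 genes would be found. Both differences use the same hybrid libraries, so sharing alone can raise the counts above these. In 20 simulations with hybrids at the U. graciosus means, at most 1 gene lay outside both parents. At most 1 gene there differed from U. graciosus, so these simulations say little about sharing. With libraries that share no animals, 6 higher and 2 lower were found where 0.868 and 0.351 would fall together by chance, and 5 and 3 where 0.876 and 0.958 would. The count fell below 162 by over 1.5 times without F (101), H (102), N (106), A (67), B (89), P (86), Q (90), R (79), S (84) or T (98).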

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

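The tests of differences between heat effects in this part were planned, and only the alternative without X, T and O was chosen after the results were seen. Each result below stands here because the heat effects of a pair of lineages differed by a test of the difference itself. For lists the test was camera with its preset correlation, and none of them held with an estimated correlation.

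TPP1, a lysosomal peptidase, differed in the test of any difference between lineages (adjusted p = 0.0438), and its heat effect differed by -1.91 on the log2 scale as U. graciosus minus U. ornatus. Chance was not excluded, since 8 of 50 splits gave at least as many genes for any difference and 5 of 50 for U. graciosus minus U. ornatus. The latter call for TPP1 was also lost without several single animals, named above.

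For hybrids minus U. graciosus, the median log2 difference of heat effects was 0.21 for OXPHOS complexes II to V, 0.36 for the proteasome and 0.093 for the cytosolic ribosome, each with adjusted p = 0.794 with an estimated correlation. It was -0.25 for fatty acid and triglyceride synthesis (adjusted p = 0.597 with an estimated correlation) and -0.051 for iron handling (adjusted p = 0.638). Among cell type markers it was -0.40 for hepatocytes, 1.003 for cholangiocytes, 1.23 for stellate cells and fibroblasts, 0.71 for macrophages, -1.07 for T and NK cells, -0.70 for erythrocytes and -2.39 for skeletal muscle. For these an estimated correlation gave adjusted p = 0.597 for muscle, adjusted p = 0.794 for T and NK cells and erythrocytes, and adjusted p = 0.638 for the others. Without X, T and O only erythrocyte and skeletal muscle of these 12 lists stayed called, and the ribosome lay the other way (adjusted p = 0.754). Skeletal muscle alone stayed called in all 18 leave-outs. However, at 36 °C hybrids D and B both held CKM (31.7 and 4.19 CPM, chosen after its values were seen), against 0 in A. Leaving out 1 library could not remove both, so the leave-outs do not separate a heat effect from muscle RNA in these livers. The stellate list (0.279) and hepatocytes (0.868) lost the call without X, macrophages without B (0.0876), and the proteasome without X (0.197) or S (0.120). The ribosome lost it without K (0.254), J (0.660) or R (0.0739) and turned lower without T (0.166). Complexes II to V lost it without A (0.172), D (0.304), I (0.0721), K (0.196), J (0.133), S (0.146) or T (0.256). Fatty acid synthesis lost it without A (0.144), I (0.0670), K (0.157), J (0.0688), Q (0.0532), R (0.0720) or T (0.108), and iron without A (0.142), X (0.348), R (0.0739), S (0.0678), T (0.218) or Uo_40 O (0.0510). Cholangiocytes lost it without A (0.0830), D (0.116), I (0.0887), X (0.454), Q (0.0532), R (0.0720) or S (0.0941). T and NK cells lost it without A (0.142), D (0.293), I (0.271), X (0.158), J (0.0688) or Q (0.119), and erythrocytes without A (0.142), X (0.766), P (0.129), Q (0.143), R (0.0647) or S (0.146).

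For hybrids minus U. ornatus, the median was 0.22 for OXPHOS complex I, 0.45 for complexes II to V, 0.20 for the mitochondrial ribosome, 0.62 for the proteasome and 1.69 for cell cycle, with adjusted p = 0.876 for cell cycle and adjusted p = 0.734 for the others with an estimated correlation. Among cell type markers it was 1.64 for stellate cells and fibroblasts, -1.13 for B and plasma cells and -1.95 for skeletal muscle. For these too it gave adjusted p = 0.734. Without X, T and O the cell cycle and stellate lists were not called (adjusted p = 0.0852 and 0.257), and cell cycle lay the other way. The proteasome and skeletal muscle stayed called in all 18 leave-outs, and the stellate list lost the call without X (0.315). For skeletal muscle, leaving out 1 library again could not remove both hybrids D and B. Complex I lost it without A (0.0901), I (0.0513), K (0.0931), E (0.0517) or N (0.239), complexes II to V without D (0.0707) or N (0.136), the mitochondrial ribosome without D (0.0507), E (0.0517) or N (0.0911), and B and plasma cells without D (0.0920) or N (0.0911). Cell cycle lost it without B (0.180), H (0.215) or O (0.115) and turned lower without X (0.410).

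For U. graciosus minus U. ornatus, the median was 0.33 for OXPHOS complex I, 0.67 for acute phase and complement and -0.86 for macrophages, with adjusted p = 0.904 for each with an estimated correlation. Without X, T and O, acute phase was not called (adjusted p = 0.238), and without Uo_40 N neither complex I (0.171) nor macrophages (0.0689) were. Complex I also lost the call without P (0.0510), and acute phase without J (0.110), T (0.237), H (0.0697) or O (0.0902).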

How the results depend on the processing

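Counts of genes past the threshold depended on the tool, and the cause was not tested except where fewer animals or a stricter threshold explain a lower count. DESeq2 gave 864 for the mean heat effect (158 in edgeR), 55 in hybrids (0), 38 in U. graciosus (0), 847 in U. ornatus (124), 80 for any difference between lineages (1), 3, 93 and 66 for the differences Hy minus Ug, Hy minus Uo and Ug minus Uo of heat effects (0, 0 and 1), 919 for Hy minus Ug (288), 466 outside both parents (162), and, for antioxidant genes, 2 in the mean heat effect (0), 1 in hybrids (0) and 5 in U. ornatus (2). Limma voom gave 530, 1 in U. graciosus, 257 in U. ornatus, 6 for any difference, 1 for Hy minus Uo and 6 for Ug minus Uo of heat effects, 1049 for Hy minus Ug and 591 outside both parents; its antioxidant counts were 1 for the mean heat effect, 1 in hybrids, 1 in U. graciosus, 7 for Hy minus Ug (3) and 26 for Hy minus Uo (16). With no low-count filter there were 73 for the mean heat effect, 60 in U. ornatus, 0 for any difference, and 1 antioxidant gene in hybrids and 1 in U. ornatus; with at least 5 CPM in 3 libraries, 2 for Ug minus Uo of heat effects. A log2 threshold of 1 left 58 for the mean heat effect, 3268 for Hy minus Uo (5580), 3045 for Ug minus Uo (5100), and 1, 6 and 7 antioxidant genes in U. ornatus, Hy minus Uo and Ug minus Uo (15). With only the groups compared there were 0 in U. ornatus, 0 for Ug minus Uo of heat effects, 174 for Hy minus Ug, and 0 antioxidant genes in U. ornatus and Hy minus Ug. At 36 °C alone the lineage counts were 13, 2925 and 2353, and at 40 °C alone 20, 2920 and 2528, for Hy minus Ug, Hy minus Uo and Ug minus Uo. Without X, T and O (chosen after seeing the data) there were 55 for the mean heat effect, 1 for Hy minus Uo and 0 for Ug minus Uo of heat effects, 0 antioxidant genes in U. ornatus and Hy minus Ug, and a hybrid position of 0.958 (exact p = 0.0625, the smallest that 5 animals allow). The halved counts (also chosen after seeing the data) and RLE factors moved no count beyond 1.5 times. Of 72 list calls, 0 stood with an estimated correlation and 21 were called by fry. Fry tests a list against no change and camera against the other genes, so the fry calls answer a different question. GPAM turned from higher to lower in U. graciosus than U. ornatus at 36 °C alone (-0.031). Leaving out 1 library gave 6 to 131 for the mean heat effect, 0 to 0 in hybrids, 0 to 0 in U. graciosus, 5 to 305 in U. ornatus, 0 to 2 for any difference, 0 to 0, 0 to 2 and 0 to 3 for the differences of heat effects, 135 to 281 for Hy minus Ug, 4775 to 6206 for Hy minus Uo, 4389 to 6062 for Ug minus Uo, 67 to 157 outside both parents, positions of 0.903 to 0.960, and 62 to 89 list calls. Antioxidant counts then ran from 0 to 2 for the mean heat effect, 0 to 3 in hybrids, 0 to 0 in U. graciosus, 0 to 5 in U. ornatus, 0 to 3 for Hy minus Ug, 8 to 25 for Hy minus Uo and 8 to 17 for Ug minus Uo. At this depth a gene with 0 counts over 3 libraries is only bounded by the floor of 3 counts.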

Other observations

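Of the tests below, those of depth, of other cell types, of tissue from outside the liver and of neighbours with placeholder names were chosen after the results were seen, and those of a mix with U. ornatus, of shared libraries, of neighbouring genes and of other splits were written before.

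The lists named next were not called between the lineages, and values of members that passed are given without reading them as a change of the group. Mitochondrial stress genes had 8 members higher and 1 lower in hybrids than in U. ornatus, among them TRAP1, the mitochondrial HSP90 (1.12), and the interferon list had 2 higher and 9 lower, among them IRF1 (-2.25). EPHX1, a hydrolase of epoxides (-2.25), SLC7A11, the cystine importer (-2.13), and MAFG, a partner of NRF2 (-0.82), were lower in hybrids than in U. ornatus. ACOT12, a thioesterase of acetyl-CoA, was higher (5.54 ± 0.44) and ACADL of fatty acid oxidation lower (-1.07). Between the parents, 6 base excision repair genes were higher and 4 lower in U. graciosus, with NTHL1 (1.37) and EXOG (1.34) among the higher. Over the 10 contrasts, the smallest adjusted p of the other lists with no call was 0.0643 for mitochondrial stress, 0.0645 for DNA damage and p53, 0.0703 for fatty acid oxidation, 0.0741 for pancreas, 0.0854 for glutathione transferases, 0.101 for xenobiotic metabolism, 0.103 for interferon, 0.139 for base excision repair, 0.139 for cholesterol synthesis, 0.143 for thrombocytes and granulocytes, 0.322 for the NRF2 pathway and 0.395 for pigment cells. Of the mitochondrial DNA-encoded OXPHOS list 0 genes were in the table, and of fat body and adipose 4 were tested, so neither list was tested.

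In each lineage 1 animal at 40 °C (X, T and O) carried most of the heat shock rise. Of RNA from other cells, 1 cell type shared by all 3 is argued against, since each list lay below the heat shock list in at least 1 of these animals by over 2 SD of random lists, by mean and by median deviation from the group companions (closest mean margin -1.24). In X the stellate list exceeded heat shock (mean deviation 2.21 against 1.28, a margin of 0.937, and median 2.00 against 0.91), so other cells may account for it there. Other cells cannot be told apart in T, where the endothelial list lay below heat shock by mean (margin -1.21) but by median within 2 SD (0.39 against 0.74), or in O, where the kidney and gonad list came near (mean 0.63 against 0.69, a margin of -0.061). A stronger response of single animals to 40 °C stays open as a biological explanation and was not tested. Lower depth, or a few genes taking the counts, would shift all genes alike. Scaling sets the median of all genes near 0, so the excess of the heat shock median is the rise itself. That excess was 0.903 in X, 0.763 in T and 0.539 in O. Random lists of the same size gave 99th percentiles of 0.445, 0.273 and 0.279. The list thus rose by more than random lists in these animals. Because scaling takes out a shift of all genes beforehand, the excess cannot tell whether depth or a few dominant genes played a part. Totals were among the lowest in O (15780346 counts), T (17299828) and X (20080212), as in U. graciosus P (17216034). Lower depth therefore stays open. An effect on only some genes, by depth or otherwise, was not tested.

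Hybrid X stood apart from the other hybrids, with a position of 0.719 and 1710 CPM of COL3A1, 1145 of SPP1 and 81.2 of MKI67 (chosen after its values were seen) beside 7251 of TF and 6841 of APOB. A U. ornatus animal labelled as a hybrid, or a mix with 10% or more of U. ornatus RNA, is argued against. X held a median of 4.42% of the U. ornatus level over 295 genes at least 16-fold lower in U. graciosus. This was under the 10% set before the result was seen. A smaller mix stays open, since 4.42% lay above the 0% to 1.35% of the other hybrids and a 10% limit cannot exclude it. Tissue from outside the liver stays open, since gut and gallbladder genes deviated by a mean of 1.27 from the other hybrids at 40 °C and muscle (0.16), kidney and gonad (0.19), pigment cell (-0.45) and pancreas genes (-1.40) by less. No biological explanation was tested.

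Of the 288 genes that differed between hybrids and U. graciosus, 202 lay towards U. ornatus and 86 away. Direction was judged by sign alone, so a gene that went past U. ornatus also counted as towards it. The 162 genes outside both parents are all among the 288 and outnumber the 86 away. Part of the 202 therefore lay past U. ornatus and not between the parents. In libraries that share no animals, 62.8% and 63.5% of the top genes lay towards U. ornatus. Simulations with hybrids at the U. graciosus means gave at most 53.1% and 54.9% there. The 70.1% in all libraries lay within what sharing can give (74.7% at most). The 20 simulations drew each gene independently, so they can understate the spread of such shares where genes vary together. Of the top genes at 1 temperature, only 13 at 36 °C and 20 at 40 °C were called. Use of the same U. graciosus libraries in both differences as the whole cause thus stays unsettled. Called genes towards U. ornatus also sat beside each other in the table more often than random genes (14 adjacent pairs, random maximum 10, permutation p = 0.0001, the smallest that 10000 draws can give), which is consistent with introgressed blocks as a hypothesis, but the 86 genes away from U. ornatus also did (3 pairs, 95th percentile 2, permutation p = 0.0107), so adjacency was not particular to the direction of U. ornatus. Among the 125 genes towards U. ornatus with a symbol there were 2 pairs (95th percentile 3, permutation p = 0.299), so neighbours with placeholder names, such as copies of 1 gene, may account for the pairs as well. No genome was used here to tell these apart.

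The counts of splits that gave as many genes include the real grouping. Splits of the same animals argued against chance for the mean heat effect (1 of 50, the real one, with 158 genes, highest other 0) and Hy minus Ug (1 of 50, 288, highest other 1). They did so too for Hy minus Uo (1 of 50, 5580, 2402) and Ug minus Uo (1 of 50, 5100, 144). For genes outside both parents the real grouping also stood alone (1 of 50, 162, 1). Those splits mixed all lineages, so the parents' differences widened the spread within groups. This can keep the other counts low, so these splits cannot tell whether genes lay outside both parents by chance. For antioxidant genes the real grouping also gave the highest count for Hy minus Ug (1 of 50, 3, highest other 1), Hy minus Uo (1 of 50, 16, 12) and Ug minus Uo (1 of 50, 15, 0). These splits regroup all genes together, so antioxidant counts can follow the differences over all genes. They cannot tell whether antioxidant genes differed in particular. The count for Hy minus Ug also became 0 without most single animals and in the fit of those lineages alone. Chance was not excluded for any difference between lineages (8 of 50, 1, highest other 2) or for the heat effects Ug minus Uo (5 of 50, 1, 9). Nothing was tested for the heat effects Hy minus Ug and Hy minus Uo and for antioxidant genes in the mean heat effect, because a real count of 0 is matched by 50 of 50 splits whatever the data (highest other 1, 2 and 2). With 3 animals a side the 10 splits are too few for a share under 0.05: the real and highest other counts were 0 and 1 in hybrids, 0 and 0 in U. graciosus and 124 and 1 in U. ornatus, and for antioxidant genes 0 and 0, 0 and 0, and 2 and 0.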
